A study of Mus musculus with 17 samples.

How the data were processed

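Gene expression was measured on 17 Agilent mouse arrays with 2 colours each. Per the labels, the Cy5 channel of every array held total RNA from the forestomach of 1 male MutaTMMouse animal and the Cy3 channel held Universal Mouse Reference RNA, a mixture from 11 mouse cell lines. No array had the dyes swapped, so every ratio is Cy5 over Cy3 and a dye effect on a probe is shared by all groups. The animals were 24 to 26 weeks old and received benzo(a)pyrene (BaP) in olive oil, or olive oil alone, by gavage every day for 28 days, and tissue was taken 72 hours after the last dose. Per the labels' protocols, 200 ng of RNA was labelled per array and the RNA integrity numbers were above 6.6. The design text calls the samples of a dose group biological replicates, so the spread between arrays includes that between animals. The groups were control (replicates 1 to 5), 25 mg/kg per day (replicates 6 to 9), 50 mg/kg per day (replicates 12 to 15) and 75 mg/kg per day (replicates 17 to 20). The protocol gives n = 5 per group. The replicate numbers skipped between the dose groups had no array among the samples, for a reason not known here.

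The authors deposited 1 scanner table per array, written by Feature Extraction 10.7.3.1 per the file headers, with spot and background intensity for both channels. Each table held 62976 spots, of which 3671 were control spots, and 432 probes had more than 1 spot. The deposited intensity values used here were the median signal and the median local background of each channel. The fixed plan assumed the mean signal, which the tables used here did not hold, so the median signal took its place and a planned comparison of the 2 columns was not run. Per the file headers, the processed signals in the same tables were corrected for background and dye by Feature Extraction; they served only as an alternative. The deposited series table held log2 values whose scale was not given in the sources used here. Set against each array's own values, it behaved as log2 of Cy5 over Cy3 after loess without background correction: the correlation was 0.998 to 0.999 over probes, the slope 0.995 to 0.998, and the column medians lay between -0.03 and -0.02. All of its columns were matched to a sample by name (0 left unmatched).

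From the intensities, background was corrected with the normexp method and an offset of 50, each array was normalized by loess with control spots at weight 0, and control spots and spots flagged as outliers were left out. Spots of 1 probe were averaged. A probe was kept when it was well above background in Cy5 on at least 4 arrays, which left 27574 probes, and each gene was represented by the probe with the highest mean brightness over all arrays, which gave 21382 genes. Of 55681 probes, 26413 were given 1 gene symbol through their RefSeq transcript in the GRCm38.p6 gene table, 0 matched several symbols and 29268 had none, with 20018 distinct symbols. Of the genes tested, 13854 had such a symbol. The array design names an older mouse build, so no coordinates are given. For a gene that was not well above background on any array of a group, the fold is a lower bound: the mean of the bright group against, per array, the higher of the lowest signal well above background and the probe's own signal, in the Cy5 channel after loess and Aquantile. Such bounds are open to dye bias, and none is given where it exceeded the fold of the fitted ratio.

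Differences were tested on log2 ratios with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all genes, threshold 0.05). All 17 arrays entered 1 fit with 4 group means. The comparisons were each dose against control, 75 against 25 mg/kg, and a straight line of log2 ratio on dose. Errors after ± are standard errors of the fit unless stated otherwise, with n = 5 for control and n = 4 for each dose. A total of 35 gene lists were fixed before the data were examined: AHR battery, NRF2 and glutathione, p53 targets, DNA repair, proliferation and mitosis, basal keratinocyte, suprabasal and cornified, hyperplasia-associated keratins and alarmins, growth factors of the EGF family, inflammation cytokines, interferon response, B cells and plasma cells, T cells and NK cells, macrophages and dendritic cells, mast cells and eosinophils, antigen presentation, fibroblasts and matrix, smooth muscle, endothelium, enteric nerve and glia, glandular stomach, pancreas acinar, adipocyte, striated muscle, red blood cells, hepatocyte, circadian clock, cholesterol and sterol synthesis, lipid oxidation and PPAR targets, ER and stress response, immediate early genes, apoptosis, Wnt with Notch and Hedgehog, retinoid handling, and housekeeping. Lists with at least 4 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over all 102 tests of a list at a dose. Beside it, camera was run with an estimated correlation, and fry was run for a shift on balance 1 way and for change in either direction.

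The genes named in the text were set by a rule fixed before the data were examined. At 75 mg/kg they were the 12 largest rises and the 12 largest falls among genes with a symbol that passed the threshold with all 4 treated arrays on 1 side of all 5 controls. At 25 and at 50 mg/kg they were the 6 largest of each kind, and for the straight line the 6 strongest of each kind. From each list, up to 4 members past the threshold at any dose were named, and Cyp1a1, Cyp1a2, Cyp1b1, Cdkn1a, Mdm2, Ccng1, Mki67 and Krt5 were named whatever their result. List members named without passing the threshold are examples chosen after their values were seen.

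The tests were checked on simulated data: in 10 runs of the comparison of 75 mg/kg with control on 21345 genes without missing values, 200 of them changed, 86.8% of changes of 1 on the log2 scale and 98.1% of changes of 2 were recovered, with a mean of 9.3 false among 194.2 calls, 0 with the wrong sign and 0 calls in an unchanged group at 25 mg/kg. The simulated noise was independent between genes and arrays, without slide effects or outlying arrays. These rates therefore check the procedure and do not give the share of false calls in the real arrays. The arrays lay on 3 slides, each of which held all 4 groups and which could not be separated from the scan day; slide was tested as a fixed block, as a random block and within each slide. Alternatives also changed the background correction, the normalization, the filter on dim probes, the choice of probe, the channel, the samples in the fit, the variance model and the array weights, and left out each array in turn. Overlaps of calls between doses, which share the 5 controls, were set beside 100 simulations of unchanged groups that shared simulated controls, beside the value for independent lists, and beside the value with the controls split into 2 and 3. Arrays give no counts, and their number limits the precision. Plots were drawn with matplotlib 3.10.9.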

Results

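The arrays asked how the forestomach of male mice responds to 28 days of oral benzo(a)pyrene, a polycyclic aromatic hydrocarbon, at 25, 50 and 75 mg/kg per day. The forestomach is the part of the rodent stomach lined by stratified squamous epithelium. Arrays were available from 5 control animals given olive oil and from 4 animals at each dose, 1 array per animal. Between 39.8% and 50.7% of probes were well above background in the forestomach channel, where the median spot signal was 75.5 to 96 over a median background of 64 to 74.5. The 3 slides held 2, 2 and 1 control arrays, 2, 1 and 1 arrays at 25 mg/kg, and 1, 2 and 1 arrays at each of 50 and 75 mg/kg.

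At 75 mg/kg the lists of interferon response, antigen presentation, keratins and alarmins, and p53 targets were higher, and that of lipid oxidation was lower, by camera with its preset correlation. With an estimated correlation the p53 call alone held (adjusted p = 0.0198), and the others had an adjusted p of 0.0607, 0.148, 0.13 and 0.13. Stfa1, a stefin that inhibits cysteine proteases, rose by 5.96 ± 0.85 on the log2 scale (adjusted p = 0.00227), or 62.3-fold. Krt16, a keratin of proliferating and wounded squamous epithelium, rose by 3.62 ± 0.57 (adjusted p = 0.00429), and Ccl8, a chemokine that attracts monocytes, rose by 3.96 ± 0.40 (adjusted p = 0.000205). Grp, the gastrin-releasing peptide, fell by 2.14 ± 0.27 (adjusted p = 0.00101), and Angptl4, an inhibitor of lipoprotein lipase, fell by 2.00 ± 0.31 (adjusted p = 0.00378). Each of these genes had all 4 treated arrays on 1 side of all 5 controls, as had every other gene named below as changed at 75 mg/kg except Sprr1b. Within the slides, Stfa1 differed by 6.49, 4.75 and 7.86, Ccl8 by 4.25, 3.70 and 4.40, and Angptl4 by -2.09, -1.85 and -2.33.

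In all, 236 of 21382 genes differed from control at 75 mg/kg, 191 higher and 45 lower, and 196 of them differed by at least 1.5-fold (165 higher and 31 lower). For 219 of the 236, the treated and control arrays did not overlap, which chance gives for 1.59% of genes taken without selection. The 236 were selected by a test on the same arrays, so their separation is no separate evidence. With slide as a fixed block, 424 genes passed (330 higher and 94 lower), and all 236 were among them. The count of lower genes differed between settings. When arrays were only centred on their medians 142 genes were higher and 3 lower, and in the fit of the compared groups alone 138 were higher and 17 lower. The counts were 159 and 25 with Agilent's processed signals, and 188 and 80 in the Cy5 channel alone. The count was 143 without control 1, 157 without control 3, 129 without control 4, and 119, 122 and 130 without replicates 17, 18 and 20 of the 75 mg/kg group.

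**Figure D1:**
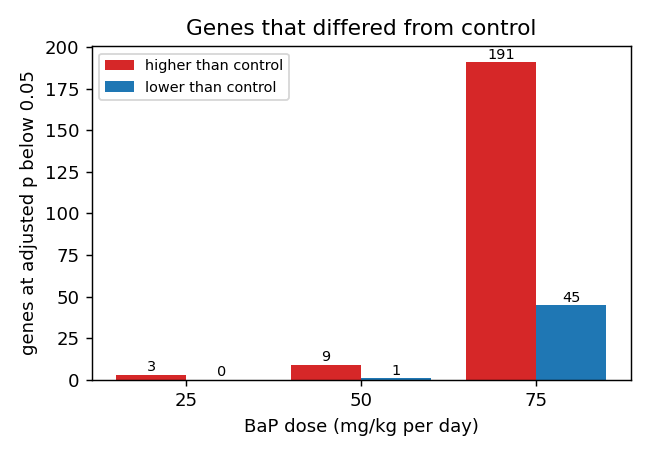
Number of genes that differed from control at adjusted p below 0.05 (vertical axis) at each dose in mg/kg per day (horizontal axis), with genes higher than control in red and lower in blue. The counts were 3 and 0 at 25, 9 and 1 at 50, and 191 and 45 at 75 mg/kg, and with arrays only centred on their medians the last pair was 142 and 3.

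Further large rises at 75 mg/kg were those of Chil4 and Defb3, which were not well above background on any control array. Chil4, a chitinase-like secreted protein, rose by 5.04 ± 0.65 (adjusted p = 0.00101), a size that rests on control signals near background, and the beta-defensin Defb3 was at least 3.85-fold higher (adjusted p = 0.00166). Stfa2 rose by 3.76 ± 0.53, Stfa2l1 by 3.42 ± 0.43 and Gm21944 by 2.99 ± 0.47 (the highest adjusted p of the 3 was 0.00429). Sprr2f, a small proline-rich protein of the cornified envelope, rose by 2.78 ± 0.52 (adjusted p = 0.0129), and Tgtp2, an interferon-induced GTPase, rose by 2.54 ± 0.55 (adjusted p = 0.0323). The Stfa, Sprr2, Chil, Tgtp and beta-defensin genes belong to families of near-identical copies, so which copy a probe measured is uncertain. Without replicate 17, 18 or 20 of the 75 mg/kg group Sprr2f did not pass (adjusted p = 0.0545, 0.0615 and 0.0563), and Tgtp2 lost its call in 8 of 17 fits without 1 array (adjusted p up to 0.114). In the controls, Stfa1 was well above background on 3 of 5 arrays, and Gm21944 and Sprr2f on 2 of 5.

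**Figure D2:**
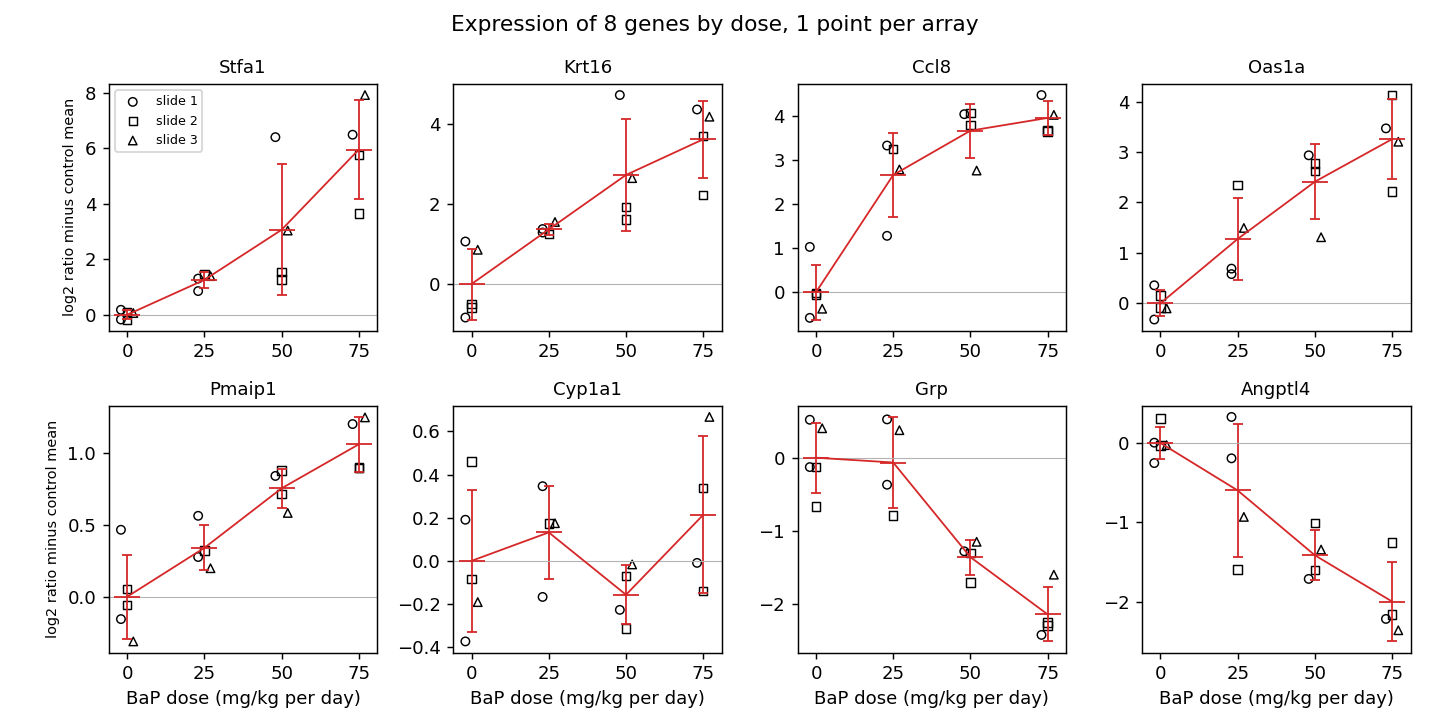
Log2 ratio minus the control mean (vertical axes) for 8 genes by dose of benzo(a)pyrene in mg/kg per day (horizontal axes), with 1 point per array, slides as marker shapes, and the mean with 1 SD in red. Stfa1, Krt16, Ccl8, Oas1a and Pmaip1 were higher and Grp and Angptl4 lower at 75 mg/kg, and Cyp1a1 differed by 0.21 (adjusted p = 0.75); with arrays only centred on their medians all 8 kept the sign of their change at 75 mg/kg, and in the Cy5 channel alone Cyp1a1 was -0.0065.

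The interferon response and antigen presentation lists were higher at 75 mg/kg by camera, but neither call held with an estimated correlation (adjusted p = 0.0607 and 0.148). Of 13 measured interferon response genes, 9 rose and 0 fell (11 rose when adjusted over the list alone). Oas1a, an antiviral oligoadenylate synthetase, rose by 3.26 ± 0.40 (adjusted p = 0.000933), and Isg15, a ubiquitin-like modifier, rose by 3.18 ± 0.47 (adjusted p = 0.00263). Their second probes gave 1.78 and 2.47 and passed as well. Ifit3, an antiviral effector, rose by 1.55 ± 0.21, and Cxcl10, a chemokine for T cells that was well above background on 1 of 5 control arrays, by 2.14 ± 0.41. The median change of the list was 1.38 (camera adjusted p = 4.26e-19), 1.38 with slide as a block, and the mean change was 1.41, 1.43 and 1.47 within the slides. Of 11 antigen presentation genes, 5 rose and 0 fell (8 rose when adjusted over the list alone): H2-K1, a class I heavy chain, by 1.85 ± 0.32, Psmb9, an immunoproteasome subunit, by 1.83 ± 0.42, B2m, the class I light chain, by 1.58 ± 0.34, Tap1, a peptide transporter, by 1.32 ± 0.23, and H2-D1, named after its value was seen, by 1.28 ± 0.21. Their median change was 1.22 (camera adjusted p = 1.08e-12), 1.28 with slide as a block, and the means were 0.94, 1.21 and 1.58 within the slides. The call of Psmb9 was lost in 12 and that of B2m in 7 of the 17 fits without 1 array (adjusted p up to 0.181 and 0.129), that of Psmb9 also with Agilent's processed signals (adjusted p = 0.0542), and that of Cxcl10 without replicate 18 or 20 of the 75 mg/kg group (adjusted p = 0.0682 and 0.0591). Probes for H2 and Oas1 genes may read related copies and are uncertain.

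The list of keratins and alarmins of hyperplastic epithelium was higher at 75 mg/kg by camera, a call that did not hold with an estimated correlation (adjusted p = 0.13). Basal and most cornified layer markers did not pass the test. Of 13 members of the keratin and alarmin list, 4 rose and 0 fell (9 rose when adjusted over the list alone). These were Stfa1, Stfa2, Krt16 and Defb14, a beta-defensin, which rose by 1.93 ± 0.34 (adjusted p = 0.00862), though with Agilent's processed signals Defb14 differed by 0.25 (adjusted p = 0.869). The median change was 2.06 (camera adjusted p = 1.13e-11), 2.15 with slide as a block, and the means were 2.26, 1.83 and 2.57 within the slides. Of 20 suprabasal and cornified genes, 2 rose and 0 fell (2 when adjusted over the list alone): Sprr1b, a cornified envelope precursor, by 3.05 ± 0.58, and Dsg1a, a desmosomal cadherin, by 1.69 ± 0.33. Sprr1b did not pass without replicate 17 or 20 of the 75 mg/kg group (adjusted p = 0.0514 and 0.0613), nor Dsg1a without replicate 20 (adjusted p = 0.0659). The median of that list was -0.02 and its mean 0.27, so median and test differed in sign, and it did not pass (camera adjusted p = 0.394). Of 10 basal keratinocyte genes, 0 passed (1 rose when adjusted over the list alone), the median was 0.01 and the camera adjusted p = 0.33. Krt5, the basal keratin, differed by -0.06 ± 0.14 (adjusted p = 0.929), but a second Krt5 probe gave 0.53 and both median centring and the Cy5 channel alone gave a positive value (0.37 and 0.41).

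The list of targets of the tumour suppressor p53 was higher at 75 mg/kg, and it was the 1 list whose call held with an estimated correlation. Of 25 members, 5 rose and 0 fell (9 rose and 1 fell when adjusted over the list alone). Pmaip1 and Bbc3, which promote apoptosis, rose by 1.06 ± 0.14 (adjusted p = 0.00111) and 0.80 ± 0.13 (adjusted p = 0.00429). Trp53inp1, a p53-induced nuclear protein, rose by 0.83 ± 0.11, though its second probe gave 0.21 and did not pass. Aen, an apoptosis-enhancing nuclease, rose by 0.48 ± 0.10, and its second probe gave 0.45 and did not pass (adjusted p = 0.119 over all probes). Aen did not pass without control 3 or 4 (adjusted p = 0.0836 and 0.0957) or without replicate 17, 18 or 20 of the 75 mg/kg group (adjusted p = 0.0695, 0.152 and 0.135). The fifth gene was Bax, named after its value was seen, at 0.39 ± 0.09 (adjusted p = 0.0491). Pmaip1 was well above background on 1 of 5 control arrays. The median change was 0.18 (camera adjusted p = 9.72e-07; adjusted p = 0.0198 with an estimated correlation), 0.21 with slide as a block, and the means were 0.33, 0.17 and 0.38 within the slides. Cdkn1a, a cell cycle inhibitor, differed by 0.39 ± 0.19 (adjusted p = 0.522), Ccng1 by 0.68 ± 0.19 (adjusted p = 0.13; 0.0475 with slide as a block), and Mdm2, which degrades p53, by 0.02 ± 0.14 (adjusted p = 0.984).

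In the AHR battery, a pair of glutathione transferases rose 72 hours after the last dose, while Cyp1a1 and Cyp1b1 did not pass the test. Cyp1a1, the classic target of the aryl hydrocarbon receptor (AHR), differed from control by 0.21 ± 0.18 (adjusted p = 0.75) and was well above background on 2 of 5 control and 2 of 4 treated arrays, and Cyp1b1 differed by -0.27 ± 0.20 (adjusted p = 0.726). Cyp1a2 did not pass the filter on dim probes. Of 12 members of the AHR battery, 2 rose and 0 fell (2 when adjusted over the list alone): the glutathione transferases Gsta1, by 1.34 ± 0.30 (adjusted p = 0.035), and Gsta2, by 1.09 ± 0.24 (adjusted p = 0.0347). These are near-identical copies and are uncertain, and leaving out 1 array ended the call of Gsta1 in 8 and of Gsta2 in 7 of 17 fits (adjusted p up to 0.146 and 0.13). Neither passed with Agilent's processed signals (adjusted p = 0.0705 and 0.272). The median change of the battery was 0.18 (camera adjusted p = 0.00188; adjusted p = 0.161 with an estimated correlation), 0.17 with slide as a block, and the means were 0.33, 0.33 and 0.26 within the slides. The median was 0.11 without control 2 and 0.26 without replicate 19 of the 75 mg/kg group. Of 18 NRF2 and glutathione genes, Slc7a11, a cystine transporter, rose by 1.27 ± 0.22 (adjusted p = 0.00816) and 0 fell (1 rose and 1 fell when adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.27).

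The list of fatty acid oxidation genes and PPAR targets was lower at 75 mg/kg by camera, a call that did not hold with an estimated correlation (adjusted p = 0.13). Of 13 members, 2 fell and 0 rose (8 fell when adjusted over the list alone), and all 13 had a negative change. Beside Angptl4, Acadm, a dehydrogenase of medium-chain fatty acids, fell by 0.46 ± 0.10 (adjusted p = 0.0264). The median change was -0.48 (camera adjusted p = 2.4e-09), -0.46 with slide as a block, and the means were -0.49, -0.57 and -0.89 within the slides. Outside the list, Adipor2, an adiponectin receptor, and Gpat4, an enzyme of glycerolipid synthesis, fell by 0.69 ± 0.13 and 0.54 ± 0.10. The adipocyte markers had a median of -0.81 and did not pass (camera adjusted p = 0.0661), and 0 of 10 passed singly (0 when adjusted over the list alone). The adipocyte list passed without control 2 (-1.11, adjusted p = 0.00488), control 3 (-0.93, adjusted p = 0.0309), replicate 19 of the 75 mg/kg group (-1.15, adjusted p = 0.0246) or replicate 6 of the 25 mg/kg group (-0.81, adjusted p = 0.0372). Its median was -0.41 without replicate 17 of the 75 mg/kg group (adjusted p = 0.168). With arrays only centred on their medians, the changes of Acadm, Adipor2 and Gpat4 were -0.08, -0.29 and -0.15 and none of these passed. In that setting the median change of all genes was 0.19. With Agilent's processed signals Gpat4 differed by -0.35 and did not pass (adjusted p = 0.235). Acadm did not pass without control 1 or 4 (adjusted p = 0.0619 and 0.0721) or without replicate 18 or 20 of the 75 mg/kg group (adjusted p = 0.121 and 0.0795).

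The enteric nerve and smooth muscle lists were lower at 75 mg/kg by camera, but neither call held with an estimated correlation (adjusted p = 0.468 for both) and no member passed over all genes. Outside them Cartpt, Tac1 and Scg2 fell, as did Grp. Cartpt, a neuropeptide precursor, fell by 1.47 ± 0.31 (adjusted p = 0.0264), Tac1, the precursor of substance P, by 1.42 ± 0.24 (adjusted p = 0.00701), and Scg2, a secretogranin of dense-core vesicles, by 1.05 ± 0.23 (adjusted p = 0.0395). The 9 enteric nerve and glia markers had a median of -0.27 (camera adjusted p = 0.0164), -0.28 with slide as a block, and the means were -0.50, -0.16 and -0.26 within the slides. The 10 smooth muscle markers had a median of -0.40 (camera adjusted p = 0.00188), -0.36 with slide as a block, and the means were -0.38, -0.50 and -0.16 within the slides. The smooth muscle median was -0.26 without replicate 18 and -0.55 without replicate 20 of the 75 mg/kg group. In neither list did a member pass when adjusted over the list alone. The nerve list did not pass without control 5 (adjusted p = 0.0959) or without replicate 17 of the 75 mg/kg group (-0.15, adjusted p = 0.152). With arrays only centred on their medians, Tac1, Cartpt and Scg2 did not pass, at -1.04, -1.03 and -0.75, nor did they with Agilent's processed signals (adjusted p = 0.0599, 0.104 and 0.0535). Cartpt did not pass without control 1 (adjusted p = 0.0783) or replicate 17, 18 or 19 of the 75 mg/kg group (adjusted p = 0.0591, 0.103 and 0.0748), and Scg2 lost its call in 10 of 17 fits without 1 array (adjusted p up to 0.149).

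A further 7 named genes fell at 75 mg/kg. Ugt2b34, a glucuronosyltransferase, fell by 1.54 ± 0.35 (adjusted p = 0.0401), Eno3, the muscle enolase, by 1.39 ± 0.15 (adjusted p = 0.000218), Pramel13 by 1.28 ± 0.29 (adjusted p = 0.0441) and Pianp by 1.19 ± 0.27 (adjusted p = 0.0403). Atp1b1, a subunit of the sodium pump, fell by 1.18 ± 0.26 (adjusted p = 0.036), Cyp4b1, a cytochrome P450, by 1.10 ± 0.26 (adjusted p = 0.0491) and Clec2i, a lectin, by 0.99 ± 0.20 (adjusted p = 0.0227). None of these 7 passed with arrays only centred on their medians, where their changes lay between -1.20 and -0.71. With Agilent's processed signals Cyp4b1 and Pramel13 differed by -0.46 and -0.64 (adjusted p = 0.855 and 0.681), and Clec2i, Pianp and Atp1b1 did not pass either (adjusted p = 0.0597, 0.0847 and 0.0796). Leaving out 1 array ended the call of Cyp4b1 in 14, Pramel13 in 13, Ugt2b34 in 11 and Pianp in 7 of 17 fits (adjusted p up to 0.184, 0.167, 0.142 and 0.161). Atp1b1 did not pass without control 1, 4 or 5 (adjusted p = 0.101, 0.095 and 0.0559) or replicate 18 or 20 of the 75 mg/kg group (adjusted p = 0.161 and 0.144), nor Clec2i without control 3 or replicate 17 or 20 (adjusted p = 0.0559, 0.0591 and 0.0985).

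Of the immune cell lists, those of macrophages and of mast cells passed at 75 mg/kg. Of 11 macrophage and dendritic cell genes, Cd207, the langerin of Langerhans cells, rose, at least 1.92-fold (adjusted p = 0.0432), and 0 fell (2 rose when adjusted over the list alone). The median was 0.46 (camera adjusted p = 0.00344; adjusted p = 0.468 with an estimated correlation), 0.51 with slide as a block, and the means were -0.07, 0.67 and 0.64 within the slides. The median was 0.69 without control 2 and 0.27 without control 4. Of 10 mast cell and eosinophil genes, Mcpt1, a mucosal mast cell protease, rose, at least 1.76-fold (adjusted p = 0.035), and 0 fell (2 rose when adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.0204; adjusted p = 0.459 with an estimated correlation), 0.26 with slide as a block, and the means were -0.03, 0.54 and 0.43 within the slides. Cd207 and Mcpt1 were not well above background on any control array, and leaving out 1 array ended their calls in 12 and 7 of 17 fits (adjusted p up to 0.135 and 0.145). Mcpt1 did not pass with Agilent's processed signals (adjusted p = 0.136). The mast cell list did not pass without control 4 (adjusted p = 0.0674) or replicate 20 of the 75 mg/kg group (0.16, adjusted p = 0.0941), and its median was 0.41 without replicate 17. B cell and T cell markers had medians of -0.67 (camera adjusted p = 0.0532) and 0.05 (camera adjusted p = 0.828), and the T cell list's mean was -0.01. Without control 2 the T cell list passed as higher (0.29, adjusted p = 0.0481). The B cell list passed as lower without control 1 (adjusted p = 0.0195), control 3 (0.0298), control 5 (0.0181), replicate 13 at 50 mg/kg (0.0434) or replicate 18 at 75 mg/kg (0.0363), and with no filter on dim probes (-0.46, adjusted p = 0.00422). Without control 2 its median was -0.19 (adjusted p = 0.448). The proliferation and mitosis list, with 26 members, had a median of 0.02 (camera adjusted p = 0.63), but passed as higher without control 2 (0.18, adjusted p = 0.000103). Mki67, a marker of cycling cells, differed by 0.15 ± 0.38 (adjusted p = 0.933). Control 2 stood apart in these lists, with B cell, T cell, antigen presentation and proliferation means of 2.26, 1.03, 1.05 and 0.71 above the control mean.

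**Figure D3:**
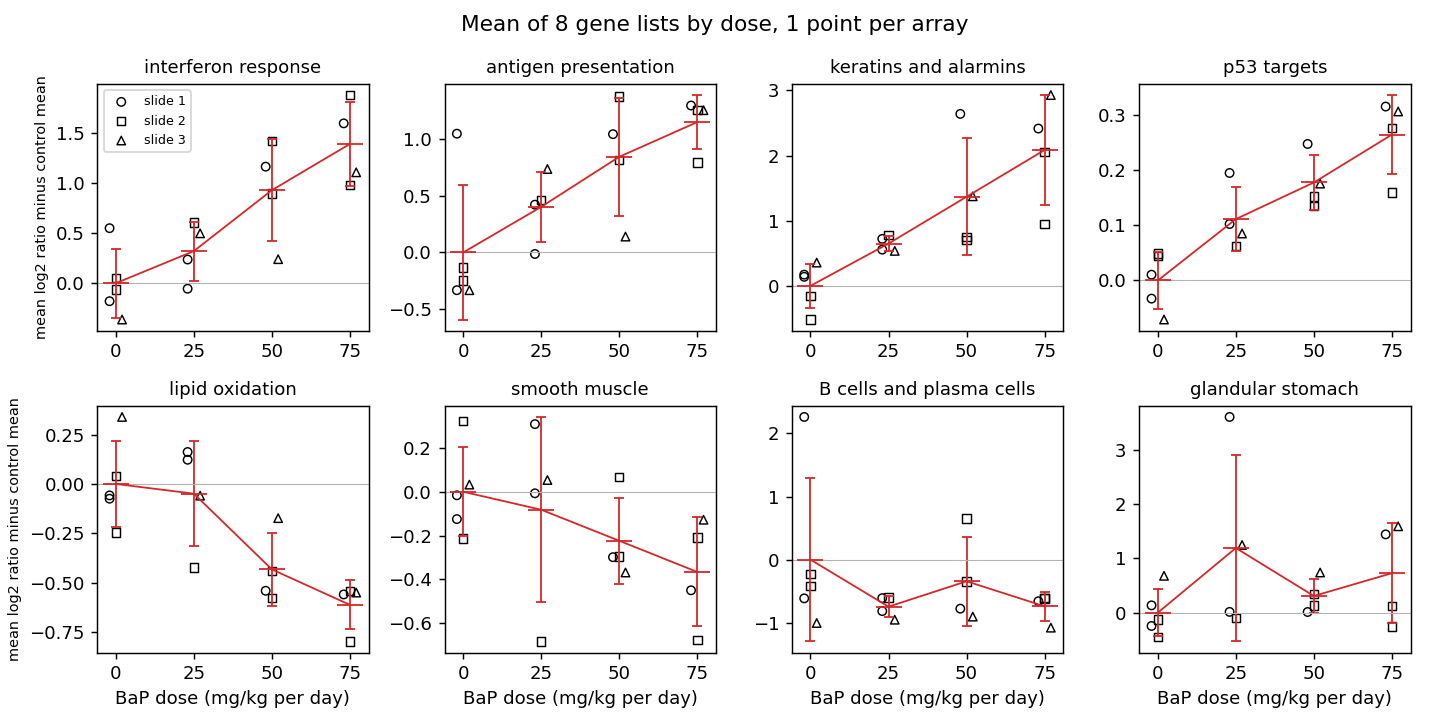
Mean log2 ratio of the members of 8 gene lists minus the control mean (vertical axes) by dose in mg/kg per day (horizontal axes), with 1 point per array, slides as marker shapes, and the mean with 1 SD in red. Interferon response, antigen presentation, keratins and alarmins, and p53 targets were higher and lipid oxidation and smooth muscle lower at 75 mg/kg by camera, the p53 call alone holding with an estimated correlation, while control 2 stood at 2.26 for B cells and replicate 7 of the 25 mg/kg group at 3.60 for glandular stomach. No list shown was tested with arrays only centred on their medians.

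At 50 mg/kg 10 genes passed, of which 1, Oas1a, was on the interferon response list. Ccl8 rose by 3.67 ± 0.40 (adjusted p = 0.0015), Oas1a by 2.41 ± 0.40 (adjusted p = 0.0416), and Bst2, an antiviral membrane protein, by 1.48 ± 0.23 (adjusted p = 0.0325). Nlrc5, an activator of class I genes, rose by 1.42 ± 0.24, Ms4a7, a membrane protein of macrophages, by 1.21 ± 0.19, Ifih1, a sensor of viral RNA, by 1.04 ± 0.17 and Trp53inp1 by 0.72 ± 0.11. Fgf9, a fibroblast growth factor, rose by 1.45 ± 0.17 (adjusted p = 0.00185), Susd4, a complement regulator, rose by 1.00 ± 0.16, and Eno3 fell by 0.86 ± 0.15. These 10 genes, 9 higher and 1 lower, were all that passed, and 1456 (6.81% of those tested) had an unadjusted p below 0.05. A total of 28 passed with slide as a block, the 10 among them, and within each slide each of the 10 kept its sign. With Agilent's processed signals Bst2, Eno3, Ms4a7 and Trp53inp1 did not pass (adjusted p = 0.0865, 0.112, 0.0925 and 0.109). The count was 2 without any 1 of controls 1, 3 and 4, replicate 9 at 25, replicates 12 and 14 at 50, or replicates 17 and 20 at 75 mg/kg, 3 without control 5, 4 without replicate 13, 28 without control 2 and 32 without replicate 15. A second Nlrc5 probe gave 0.43 at 75 mg/kg and did not pass there, against 1.93 ± 0.24 for the first.

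At 50 mg/kg, 7 lists passed camera. Interferon response had a median of 0.85 (1 rose, 9 when adjusted over the list alone; adjusted p = 0.13 with an estimated correlation), antigen presentation 0.84 (0 and 5; adjusted p = 0.161 with an estimated correlation), and keratins and alarmins 1.35 (0 and 6; adjusted p = 0.161 with an estimated correlation). The p53 targets had a median of 0.14 (1 and 5; adjusted p = 0.0557 with an estimated correlation), macrophages 0.45 (0 and 1; adjusted p = 0.459 with an estimated correlation) and the circadian clock 0.22 (0 and 0; adjusted p = 0.475 with an estimated correlation). Lipid oxidation had a median of -0.32 (0 fell, 4 when adjusted over the list alone; adjusted p = 0.161 with an estimated correlation). With slide as a block these medians were 0.86, 0.86, 1.49, 0.13, 0.44, 0.21 and -0.31 in the same order, and the circadian clock no longer passed (adjusted p = 0.103). Within slides, the interferon means were 0.98, 1.16 and 0.60, those of keratins and alarmins 2.48, 1.06 and 1.02, those of the p53 targets 0.26, 0.10 and 0.25, and those of macrophages -0.13, 0.65 and 0.58. By fry for a shift 1 way, interferon response and p53 targets passed (adjusted p = 0.029 and 0.0108). Keratins and alarmins, antigen presentation and macrophages did not (adjusted p = 0.0923, 0.102 and 0.363). For change in either direction, fry gave an adjusted p of 0.00274, 4.19e-05, 0.0168, 0.146 and 0.464 for these 5 lists in the same order.

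At 25 mg/kg 3 genes rose and 0 fell. Ccl8 rose by 2.66 ± 0.40 (adjusted p = 0.0354), Fgf9 by 1.39 ± 0.17 (adjusted p = 0.00657) and Susd4 by 1.05 ± 0.16 (adjusted p = 0.0354), and for each all 4 treated arrays lay above all 5 controls. With slide as a block Fgf9 alone passed, and Ccl8 and Susd4 had an adjusted p of 0.0707, and with Agilent's processed signals of 0.114 and 0.16. By limma, 697 genes (3.26% of those tested) had an unadjusted p below 0.05, a smaller share than the 0.05 that unchanged genes would give. The count was 0 without replicate 6 or replicate 9 at 25 mg/kg, 2 without control 1, replicate 7 at 25 mg/kg or replicates 13 and 15 at 50 mg/kg, and 1 without any other array.

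At 25 mg/kg 11 lists passed camera, and none of these calls held with an estimated correlation. The higher lists were keratins and alarmins (median 0.83; adjusted p = 0.459 with an estimated correlation), antigen presentation (0.47; 0.468), interferon response (0.28; 0.468), growth factors of the EGF family (0.21; 0.468), the AHR battery (0.19; 0.148), NRF2 and glutathione (0.17; 0.468) and p53 targets (0.11; 0.258). The glandular stomach list had a median of 1.59 (adjusted p = 0.422 with an estimated correlation), and 1 array, replicate 7, had a mean of 3.60 for it. The lower lists were B cells (-0.75; adjusted p = 0.468 with an estimated correlation), T cells (-0.27; 0.468) and proliferation (-0.12; 0.722), in each of which control 2 was high. Over all genes 0 members passed in any of the 11, and when adjusted over the list alone 1 of the AHR battery rose. With slide as a block all 11 still passed, but within slides the signs of the means differed for interferon response (-0.09, 0.61 and 0.86), antigen presentation (-0.15, 0.66 and 1.07), NRF2 (0.29, 0.09 and -0.11), the EGF family (0.31, 0.38 and -0.01), B cells (-1.54, -0.28 and 0.05), T cells (-0.76, 0.04 and 0.21) and proliferation (-0.40, -0.12 and 0.29).

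A straight line on dose asked which genes had a slope, which does not show an even change from dose to dose. Grp, for example, differed from control by -0.07 at 25 and -1.36 at 50 mg/kg. Grip1, a scaffold protein of synapses and epithelia, rose by 0.0216 per mg/kg (adjusted p = 9.39e-05), Ifih1 by 0.0194, Oas1a by 0.0439, Pmaip1 by 0.0143, Bst2 by 0.0246 and Ms4a7 by 0.0198 on the log2 scale. Eno3 fell by 0.0184 per mg/kg (adjusted p = 6.87e-05), and the other falling slopes were -0.0301 for Grp, -0.0272 for Angptl4, -0.0195 for Tac1, -0.00935 for Adipor2 and -0.00738 for Gpat4. In all, 288 genes passed, 224 with a rising and 64 with a falling line. When slide was a block 549 passed, the 288 among them, and with arrays only centred on their medians 166 rose and 6 fell, against 270 and 141 in the Cy5 channel alone.

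The comparison of 75 with 25 mg/kg tested whether the highest and lowest doses differed. Chil4 was higher at 75 mg/kg by 4.66 ± 0.69 (adjusted p = 0.0192), Stfa2l1 by 2.75 ± 0.45 (adjusted p = 0.0302) and Grip1 by 1.31 ± 0.16 (adjusted p = 0.00689). Chil4 was well above background on 1 of 4 arrays at 25 mg/kg, so the size of its difference rests on signals near background. Defb3 was higher as well (adjusted p = 0.0302), and no size is given because it was well above background on 0 of 4 arrays at 25 mg/kg. Grp was lower, at -2.07 ± 0.29 (adjusted p = 0.0176), as was Eno3, at -0.99 ± 0.15 (adjusted p = 0.0302). These were among 13 genes, 7 higher and 6 lower, and 32 passed with slide as a block, the 13 among them. The difference between the doses was 0.26 ± 0.18 for Fgf9 and 0.04 ± 0.17 for Susd4 and did not pass for either. The count was 0 with Agilent's processed signals, with median centring or with the fit of the compared groups alone, 2, 1 and 1 without replicates 6, 7 and 9 at 25 mg/kg, 0, 1 and 3 without replicates 17, 18 and 20 at 75 mg/kg, 6, 6 and 7 without controls 1, 3 and 4, 24 without replicate 12 at 50 mg/kg, and 37 without replicate 19 at 75 mg/kg.

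The doses shared calls. Ccl8, Fgf9 and Susd4 passed at all 3 doses in the same direction, and all 10 genes of 50 mg/kg passed at 75 mg/kg. The overlap of 50 with 75 mg/kg was 2 without control 1, 3 or 4, 32 without replicate 15 at 50 mg/kg, and 1 with arrays only centred on their medians. Simulated unchanged groups that shared simulated controls had 0 genes in common for each pair. Groups drawn without change have few or no calls to share, so that value was near certain in advance and is no evidence. Independent lists would share 0.0825 genes between 50 and 75 mg/kg, 0.0268 between 25 and 75, and 0.00126 between 25 and 50. With the controls split into 2 and 3, the doses of 50 and 75 mg/kg shared a median of 2 genes and the other pairs 0. At an unadjusted p below 0.05, the shared genes numbered 277, 330 and 774 for 25 with 50, 25 with 75 and 50 with 75 mg/kg, against simulated medians of 203.5, 201 and 203, values for independent lists of 24.7, 36.4 and 74.6, and split-control medians of 82, 121 and 309.5. The simulations drew every gene and array independently, so their medians leave out any structure shared by genes, such as that of control 2 or of slide.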

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

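The tests of a macrophage score, of a smooth muscle score and of an adipocyte score within arrays, of immune markers without control 2, and of regroupings within slides were chosen after the results were seen, and the others before. In each of 380 groups of 4 or 5 arrays, 1 array was called far from the rest when its gap to the nearest other array took up too much of the group's range, which chance gives for about 1 group in 20. This held for 28 of the groups, and 1 array can stand apart in several measures. Values are log2 ratios minus the control mean, as all below.

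Control 2 lay far from the other controls in 8 measures: Isg15 (1.24), Bst2 (0.38), Mki67 (1.79) and the means of the B cell (2.26), T cell (1.03), antigen presentation (1.05), red blood cell (2.59) and apoptosis (0.24) lists. Control 1 did so for the circadian clock (-0.40). At 25 mg/kg, replicate 7 did so for Tgtp2 (-0.86), Grip1 (-0.077) and Ms4a7 (-0.023), replicate 6 for Pramel13 (0.48), replicate 8 for the T cell list (-0.094) and replicate 9 for Aen (0.18). At 50 mg/kg, replicate 12 did so for Defb3 (1.47), Aen (0.42) and Gpat4 (-0.43), replicate 13 for Susd4 (1.34) and the smooth muscle list (0.067), and replicate 15 for Mdm2 (-0.40). At 75 mg/kg, replicate 17 did so for Cyp1b1 (-0.66) and the retinoid list (0.12), replicate 18 for the lipid oxidation list (-0.80), replicate 19 for Cdkn1a (0.024) and the antigen presentation list (0.79), and replicate 20 for the inflammation cytokine (-0.19) and B cell (-1.08) lists. No explanation was tested for these single arrays.

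The interferon response genes were higher at 75 mg/kg by a median of 1.38. A joint rise of B cells, T cells and macrophages is argued against as the whole source. Their pooled markers had a median change of 0.042 (mean -0.063 ± 0.32 over arrays). The bound of 0.69 was computed from the list's own change by a rule set in advance. The median lay below it by barely more than 2 standard errors of the array means. Without control 2 the pooled mean was 0.25 ± 0.071 against a bound of 0.76, clearly below it by more than 2 standard errors. The pool averages B cell and macrophage lists that moved in opposite directions, and 8 of 16 B cell markers were measured. It therefore cannot address a rise of 1 cell type. Slide is argued against by the blocked median of 1.38 with the same sign within each slide, and the reference channel by a change of 0.023 ± 0.016 in Cy3 alone. With the macrophage score as a covariate the list's mean change was 1.27 ± 0.31, which lies above its bound of 0.69 by less than 2 standard errors, so a change in macrophages alone remains open. A response of the tissue to the dose may be the source. It stays a hypothesis, because macrophages remain open and the list's camera call did not hold with an estimated correlation.

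The enteric nerve list was lower at 75 mg/kg, by a mean of -0.25 ± 0.15. The smooth muscle markers changed by -0.37 ± 0.15, as less muscle layer in the section would predict, in a test that could have come out the other way. With the smooth muscle score of each array as a covariate the nerve change was -0.10 ± 0.14, against a bound of -0.13, too wide to decide. The protocol took random sections, so a different share of muscle may account for the fall of the list, and for this list an effect of the dose on nerves cannot be told apart from it. Grp, Cartpt, Tac1 and Scg2, which are outside the list, changed by -2.14, -1.47, -1.42 and -1.05. They were named for the size of their fall, and whether a share of muscle accounts for them was not tested.

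The lipid oxidation list was lower at 75 mg/kg, by a mean of -0.61 ± 0.11. The adipocyte markers outside the list changed by -0.72 ± 0.69, an error too wide to decide whether fewer fat cells in the section may account for it. With the adipocyte score as a covariate the change was -0.58 ± 0.14, which lies beyond its bound of -0.31 by less than 2 standard errors, so fat content may account for a part. The list still lay below control by more than 2 standard errors. Replicates 17, 18, 19 and 20 at 75 mg/kg had adipocyte means of -1.42, -1.69, 0.28 and -0.06 and lipid means of -0.56, -0.80, -0.54 and -0.55. Control 2 had -1.47 and -0.07. These values argue against fat content, as these markers measure it, as the whole source.

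Other splits of the arrays into groups of the same sizes were drawn for each count. At 25 mg/kg, 1 of 100 splits called as many genes as the real 3, the real one itself, and the highest other called 2. At 75 mg/kg, 1 of 100 did for the real 236 and the highest other called 126, by parting control 2 and the treated arrays from the other controls, and for 75 against 25 mg/kg 1 of 35 did for the real 13 and the highest other called 3. At 50 mg/kg, 2 of 100 splits called as many as the real 10, and the highest other called 974. It set controls 1 and 5 with replicates 12 and 15 at 50 mg/kg, which lie on slides 1 and 3, against the rest and so followed the slide but for control 2; with slide as a block the real count was 28. For the straight line, 2 of 100 orders of the doses called as many as the real 288, and the highest other called 761, with mean doses of 41.7, 17.9 and 56.2 mg/kg on the slides against 29.2, 39.3 and 37.5 in the real order. Splits that call several times the real count point to a structure of the samples.

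Because those splits were drawn without regard to slide, the arrays were also regrouped within slides only. Of 36 such regroupings, 1, the real one, called as many genes at 25 mg/kg (real 3, highest other 0), at 50 mg/kg (real 10, highest other 8) and at 75 mg/kg (real 236, highest other 126). Each share is under 0.05, but it is the smallest that 36 regroupings allow and was not adjusted for the several counts tried. The straight line gave 1 of 100 orders (real 288, highest other 2), a share under 0.05 as well. The comparison of 75 with 25 mg/kg has 18 regroupings, too few for a share under 0.05 (real 13, highest other 1). With slide also as a block, 1 of 36 regroupings called as many at 50 mg/kg (real 28, highest other 11) and at 75 mg/kg (real 424, highest other 223), and 2 of 100 orders did for the straight line (real 549, highest other 943). At 25 mg/kg, 3 of 36 did (real 1, highest other 79), so with the block chance cannot be excluded there. Since these highest others, of 943 and 79, came with the block, the structure is not of the slide alone.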

How the results depend on the processing

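Scaling between arrays, and leaving out control 2 with replicate 7 at 25 mg/kg, were chosen after the data were seen, and the other tests before. The main counts were 3, 10 and 236 genes at 25, 50 and 75 mg/kg, 288 for the straight line and 13 for 75 against 25 mg/kg, with an overlap of 10 and 30 list calls. Where a count moved, the cause was not tested. Signals were close to background for many probes, which limits dim genes, and a comparison of median with mean signal was not run. Aquantile left the log ratios as they were by construction. Reversals were 49, all of genes and lists that did not pass in the reported result, and 1 passed on the other side, the T cell list without control 2 (adjusted p = 0.0481). Turns of sign within a slide by genes that did not pass are not in this count.

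With slide as a fixed block the counts were 1, 28, 424, 549 and 32 with an overlap of 27, and as a random block 21, 383, 489 and 32 from 50 mg/kg on with an overlap of 20. Median centring gave 0, 1, 145, 172 and 0 with an overlap of 1. Agilent's processed signals gave 1 at 25 mg/kg and 0 for 75 against 25, and the Cy5 channel alone gave 1 at 25 mg/kg. No filter on dim probes gave 1 and 6 at 25 and 50 mg/kg with an overlap of 6, and scaling between arrays gave 16 at 50 mg/kg with an overlap of 16. Array weights gave 80 at 50 mg/kg and 34 for 75 against 25 with an overlap of 76, and the compared groups alone gave 155 at 75 mg/kg and 0 for 75 against 25. Leaving out control 2 and replicate 7 together gave 6, 50 and 1 at 25, 50 and 75 against 25, with an overlap of 47. The overlap was 2 with split controls and 774 at an unadjusted p of 0.05. List calls numbered 1 with an estimated correlation, 7 by fry and 12 by fry in either direction. Of the 12 lists called at 75 mg/kg, 11 lost the call with an estimated correlation, 7 by fry and 6 by fry in either direction.

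Without 1 array each, the counts ranged from 0 to 2 at 25 mg/kg, 2 to 32 at 50, 119 to 289 at 75, 192 to 403 for the straight line and 0 to 37 for 75 against 25, the overlap from 2 to 32 and the list calls from 28 to 38. Over all alternatives, values of named genes counted as kept in 2149 cases. They lost a call in 398, gained one in 3, moved without a test in 53 and turned sign in 11. In the fits, kept means the same direction and side of the threshold. Within slides 1, 2 and 3, the 60, 66 and 40 kept cases had no threshold and lay within the residual SD of the reported change. A turn of sign there was counted only for genes that passed. For lists at 75 mg/kg the cases were 739 kept, 43 lost, 30 gained and 38 with the test turned. With processed signals the EGF family, mast cell and ER stress lists did not pass at 75 mg/kg.

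For genes, the sign of the change turned for Krt5 (0.37) and Cyp1b1 (0.033) with median centring, Cyp1a1 (-0.0065), Mdm2 (-0.022) and Krt5 (0.41) in Cy5 alone, and Mdm2 (-0.0063) with array weights. Outside the count of turns, the sign also differed within slide 1 for Mki67 (-0.35), Krt5 (0.25) and Mdm2 (-0.10). Within slide 2 it differed for Mdm2 (-0.053), Cyp1a1 (-0.089) and Cyp1b1 (0.16). For lists, the direction of the test turned, which need not turn the sign of the median given in brackets: T cells (0.21), cholesterol (0.056) and housekeeping (-0.020) with processed signals. The test also turned for inflammation (-0.0083) and cholesterol (0.014) with no filter, cholesterol (0.018), immediate early genes (-0.016) and apoptosis (-0.0041) with slide as a block, and cholesterol (0.014) by fry. Leaving out control 2 and replicate 7 turned the test for T cells (0.29), red blood cells (0.088), immediate early genes (-0.067) and apoptosis (0.061). Without 1 array each, Mki67 ranged from -0.067 to 0.60, Mdm2 from -0.063 to 0.098, cholesterol from -0.11 to 0.11, T cells from -0.083 to 0.29, red blood cells from -0.71 to 0.088 and immediate early genes from -0.086 to 0.089. Apoptosis ranged from -0.063 to 0.061, fibroblasts from -0.18 to 0.062, proliferation from -0.066 to 0.18, inflammation from -0.11 to 0.20 and suprabasal genes from -0.11 to 0.12. The cause was not tested.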

Other observations

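The tests and lists in this part were fixed before the data were examined; the choice of examples was made after. Growth factors of the EGF family, which drive keratinocyte growth, had a median change of 0.21 at 75 mg/kg over 9 members (camera adjusted p = 0.0164; adjusted p = 0.459 with an estimated correlation), with 0 past the threshold singly (2 rose when adjusted over the list alone) and means of 0.64, 0.08 and 0.36 within the slides. The list did not pass without control 2 (adjusted p = 0.08) or replicate 17 of the 75 mg/kg group (adjusted p = 0.0966), and its median was 0.35 without replicate 19. Among them Epgn, an epithelial mitogen, differed by 0.91 ± 0.28 (adjusted p = 0.18). ER and stress response genes had a median of 0.16 over 13 members (camera adjusted p = 0.0479; adjusted p = 0.409 with an estimated correlation), with 0 past the threshold (1 rose when adjusted over the list alone), and did not pass with slide as a block (adjusted p = 0.0618) or in 7 of 17 fits without 1 array (adjusted p up to 0.146). Of 11 retinoid handling genes, Aldh1a3, which makes retinoic acid, rose by 0.88 ± 0.20 (adjusted p = 0.0467) and 0 fell (1 rose and 2 fell when adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.262); its call ended in 12 of 17 fits without 1 array and with Agilent's processed signals. Of 12 housekeeping genes, B2m rose and 0 fell (1 when adjusted over the list alone); the median was -0.09 and the mean 0.04, so they differed in sign (camera adjusted p = 0.7).

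The other lists did not pass camera at 75 mg/kg, and 0 of their members passed over all genes. The medians were 0.04 for DNA repair (adjusted p = 0.267), 0.03 for inflammation cytokines (adjusted p = 0.63; 2 rose when adjusted over the list alone), -0.06 for fibroblasts and matrix (adjusted p = 0.652), 0.06 for endothelium (adjusted p = 0.515) and 0.31 for glandular stomach (adjusted p = 0.0644; 0.0454 with slide as a block). They were -0.37 for striated muscle (adjusted p = 0.0589; 0.0137 with slide as a block; 1 fell when adjusted over the list alone), -0.48 for red blood cells (adjusted p = 0.318), -0.81 for hepatocyte markers (adjusted p = 0.183) and 0.25 for the circadian clock (adjusted p = 0.112). They were 0.01 for cholesterol and sterol synthesis (adjusted p = 0.994, with the test in the other direction), -0.03 for immediate early genes (adjusted p = 0.819, with the test in the other direction), -0.01 for apoptosis (adjusted p = 0.942) and 0.08 for Wnt with Notch and Hedgehog (adjusted p = 0.126). For pancreas acinar markers 3 members were measured, too few for a test, with changes of 1.67 for Clps, 1.10 for Ctrb1 and 0.09 for Cela1. Leaving out 1 array brought some of these lists past the threshold. The glandular stomach list passed without replicate 7 or 8 at 25 mg/kg (adjusted p = 0.0123 and 0.0471) or replicate 18 or 19 at 75 mg/kg (0.0369 and 0.0168). The striated muscle list passed without control 2 (adjusted p = 0.0481), replicate 13 at 50 mg/kg (0.0474) or replicate 19 or 20 at 75 mg/kg (0.0438 and 0.038). The hepatocyte list passed without control 5 (adjusted p = 0.0175) or replicate 17 at 75 mg/kg (0.00231), and the circadian clock without control 4 (adjusted p = 0.0299) or replicate 17 (0.0228). The hepatocyte median ranged from -1.38 without replicate 17 to -0.24 without control 1, and the clock median from 0.12 without control 1 to 0.34 without replicate 17. In the glandular stomach list the mean of replicate 7 at 25 mg/kg was 3.60, against a control SD of 0.43. Replicates 17, 18, 19 and 20 at 75 mg/kg had glandular stomach means of 1.44, 0.13, -0.25 and 1.59. Their pancreas means were 2.98, 0.39, -0.23 and 0.67, so replicate 17 contributed most to the pancreas changes.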
